A study of Mus musculus with 16 samples.

How the data were processed

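The samples were 16 mouse small intestinal libraries of strain C57B6 per the labels, in 4 groups by genotype and sample type: 4 WT and 5 Mfge8 null libraries of isolated enterocytes, and 4 WT and 3 Cd36 null libraries of small intestine. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, RNA was purified with a column kit for small inputs (enterocytes) or for lipid-rich tissue (small intestine), and libraries were made with a forward 3' tag kit with a unique molecular identifier (UMI) module and sequenced as single-end reads. A 3' tag library gives about 1 read per transcript near its polyadenylated end, so gene length hardly enters the values, and changes elsewhere in a transcript are not measured.

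Per the submitters' processing notes, the tools were Trimmomatic 0.38.1, HISAT2 2.1.0, HTSeq 0.91 and DESeq2 2.11.40 with the genome build mm10; their order, settings, the use of the UMIs and the strand setting of the counting were not given in the sources used here. Reads without UMI collapsing are not independent molecules, so intervals and floors cover counting error only. The deposited values were a normalised signal, which the authors gave in 2 tables, 1 per experiment, with 24420 features each. Within each library the values were whole multiples of the smallest positive value to within 1e-06 for 100% of values, so they were taken as read counts divided by 1 size factor per library, and whole reads were recovered. Size factors were 0.855 to 1.28 in the Mfge8 table and 0.939 to 1.105 in the Cd36 table. For WT 4 and null 3 of the Mfge8 table the size factor lies so close to 1 that the step is less certain, and a count test was also run without them. The tables were normalised separately, so tests were made within a table.

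Depth was 1618369 to 2459812 reads per library in the Mfge8 table and 850297 to 1000694 in the Cd36 table, and the 10 most abundant genes took 14.3% to 19.2% and 9.75% to 10.02% of the reads. The biological coefficient of variation was 22.0% in WT and 22.9% in null enterocytes, and 1.85% and 2.15% in the intestine groups. Pairs of libraries were compared by a chi-square test of their reads over genes with at least 20 reads in the pair. Because libraries of 1 genotype in the Cd36 table agreed at about sampling noise, they were counted as 1 sample per genotype: its calls are reported as differences between 2 preparations, a name for the 2 groups of libraries, with ranges over libraries in place of SDs.

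Genes with a value of at least 5 in at least as many libraries as the smaller group were tested (9432 and 9314 genes). The main test was limma 3.58.1 with a trend on log2(value + 1), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, run in R 4.3.3. Log2 changes are on the log2(value + 1) scale, which understates the change of low genes. The targeted genes were also tested by an exact permutation test over all splits. Of 46 gene lists, 27 of pathways and 19 of cell type, region and sex markers, those with at least 3 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists; the targeted gene was left out of its own comparison, and sex-linked genes were only described. Camera with an estimated correlation and fry were alternatives. A list's median was also placed among the medians of 10000 random lists of matched expression. Some list members were found under older symbols, and the mitochondrially encoded genes, Trac, Trdc, Ighm, Igha, Igkc and Sh2d6 had no values in the tables used here.

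Overlap of calls was tested with Fisher's exact test per direction, the difference between experiments with limma on the joined log2 values, and the correlation of fold changes against 100 random exchanges of libraries within each table. Calls within 10 Mb of the targeted gene were compared with those elsewhere by Fisher's exact test, with RefSeq positions on mm10 for 99.8% of tested genes. The procedures were tested on simulated data with 200 changed genes: in the Mfge8 comparison (9427 genes) 12.5%, 37.9% and 100% of genes changed 1.5, 2 and 4 fold were called, with 3 false among 99 calls. In the Cd36 comparison (9290 genes) the shares were 43.1%, 68.2% and 98.4%, with 6 false among 142 calls. Its simulation used the spread between its libraries, a dispersion of 0.000396 against 0.0508 in the Mfge8 comparison. The Cd36 shares and false calls therefore hold for that spread and not for a spread between mice. In both simulations all genes had the same dispersion. The shares and false calls of either comparison thus do not cover genes that vary more between libraries. On these data, simulated without correlation between genes, the list test called the moved list and 0 of 20 unmoved lists in either comparison.

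Named genes were chosen by a rule fixed before the data were examined, as were the groups, tests, lists and most alternatives. The rule takes the targeted gene, then the 10 largest rises and 10 largest falls past the threshold without overlap of null and WT libraries and with a higher group mean of at least 20, leaving out predicted genes, immunoglobulin and T cell receptor segments and features without a symbol. It adds up to 4 members per list with the smallest adjusted p past the threshold, up to 10 genes past the threshold in both experiments, and the 5 largest positive and 5 largest negative differences between experiments. Where no more than a few members of a list passed, up to 2 with the largest changes were given with values. Alternatives were pseudocounts of 0.5 and 5, a filter of 20 or none, TMM rescaling, no trend, array weights, a replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on the whole reads, windows of 5 and 20 Mb, and leaving out each library. Figures were drawn with matplotlib 3.10.9.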

Results

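Gene expression was measured by 3' tag RNA sequencing in the small intestine of mice that lacked Mfge8 or Cd36. MFGE8 is a secreted glycoprotein that binds integrins, and CD36 is a membrane receptor that takes up long-chain fatty acids. The first experiment held 9 libraries of isolated enterocytes, the absorptive cells of the gut epithelium, from WT (4 libraries) and Mfge8 null (5 libraries) mice. The second held 7 libraries of small intestinal tissue from WT (4 libraries) and Cd36 null (3 libraries) mice. Enterocyte libraries held 1618369 to 2459812 reads assigned to genes, with reads on 11774 to 12578 genes. Intestine libraries held 850297 to 1000694 reads, with reads on 12214 to 12498 genes. Levels are given as normalised read counts, that is, reads divided by 1 size factor per library. The experiments were normalised in separate tables, so levels were tested only within each table.

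Replicate libraries of the enterocyte experiment differed from each other by far more than counting error, with a chi-square per degree of freedom of 6.26 to 20.2 over the 16 pairs of the same genotype. In the intestine experiment the 9 pairs of the same genotype had values of 0.987 to 1.117, and the 12 pairs between genotypes had values of 2.14 to 2.275. Of these 9 pairs 5 differed by more than sampling noise by the chi-square test (p from 2.41e-12 to 0.0263). With values this close to 1 the intestine libraries of each genotype differed by about the sampling noise, and were counted as 1 sample per genotype. All 7 intestine libraries held both the female-specific transcript Xist, and the Y-linked gene Ddx3y. Xist was at 441 to 498 normalised reads in WT (mean 472) and 319 to 359.97 in null libraries (mean 340.2), a log2 change of -0.47 without overlap, and Ddx3y had means of 44.6 and 44.0. None of the 9 enterocyte libraries held a read of Xist, and all 9 held Y-linked transcripts. The labels do not say that libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

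**Figure D1:**
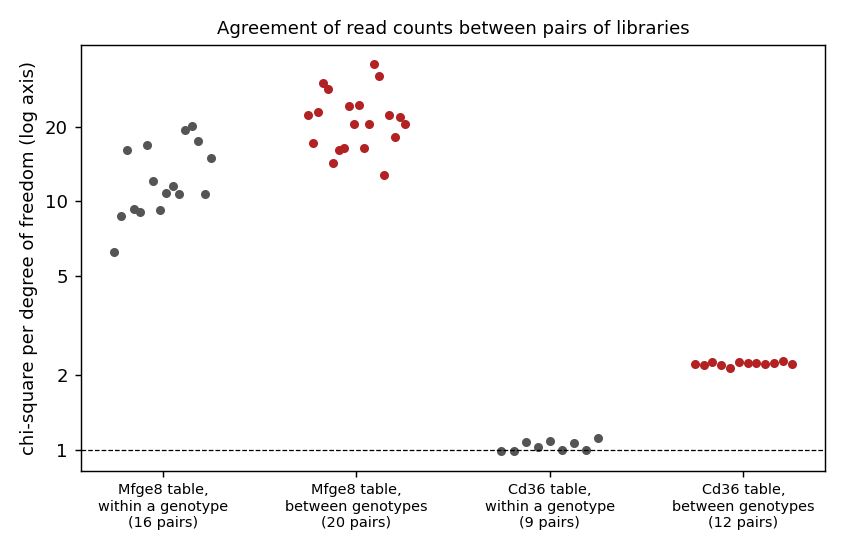
Chi-square per degree of freedom (log axis) between the read counts of every pair of libraries, within and between genotypes of each table; the dashed line marks 1, the value for counting error alone. The 9 pairs within a genotype of the Cd36 table lie between 0.987 and 1.117, and the 16 such pairs of the Mfge8 table between 6.26 and 20.2.

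The enterocyte comparison addressed which genes differ in expression when Mfge8 is absent. Mfge8 itself (chromosome 7, 79133768 to 79149060, mm10) was low in WT enterocytes, at 14.8 ± 6.70 normalised reads (SD, n = 4), and was 3.45 ± 2.43 in null enterocytes (SD, n = 5), 23.3% of WT. The WT libraries held 8 to 21 reads of the gene and the null libraries 2 to 7. All 4 WT libraries (23.4, 11.4, 16.5 and 7.94) lay above all 5 null libraries (3.92, 2.19, 1.998, 7.50 and 1.64). The log2 change was -1.87 with a standard error of 0.46 (adjusted p = 0.0362 by limma), and the 2-sided exact permutation test gave p = 0.0159, where the smallest possible value is 0.00794. A 3' tag lies at the end of the transcript and the deleted part of the gene is not given in the labels, so residual tags do not show whether functional transcript remained. The call for Mfge8 was lost in 10 of 20 alternative settings.

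In Mfge8 null enterocytes all 7 measured MHC class II genes and 4 of 11 antimicrobial and inflammatory genes rose, while 6 of 15 triglyceride lipases and carboxylesterases, 5 of 16 xenobiotic genes and 4 of 19 genes of peroxisomal and microsomal fatty acid oxidation fell. With an estimated correlation none of these lists kept its call (adjusted p = 0.163 for MHC class II, 0.338 for the lipases and 0.378 for the other 3). H2-Aa, a chain of the MHC class II molecule, rose from 176 ± 77.6 to 1558 ± 445 normalised reads, and Reg3b, a secreted antibacterial lectin, rose from 7400 ± 2704 to 51334 ± 25356. Aadac, an esterase of the endoplasmic reticulum, fell from 476 ± 209 to 83.6 ± 41.2 (SD, n = 4 WT and 5 null libraries, here and in the values that follow). By limma, 303 of 9432 genes passed an adjusted p of 0.05, 149 of them higher and 154 lower in null enterocytes, and 1498 had an unadjusted p under 0.05. Of the 303 genes, 191 changed by more than 1 on the log2 scale. WT and null libraries did not overlap for 250 of the 303, and for 606 (6.42%) of all genes tested, where chance gives 1.59%. The number of genes depended on single libraries: it was 140 without WT 1, 173 without WT 2, 185 without null 3 and 199 without null 5.

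All 7 measured MHC class II genes rose, with a median log2 change of 2.67 (camera adjusted p = 5.83e-16; adjusted p = 0.163 with an estimated correlation). All 7 also passed when adjusted over the list alone. Besides H2-Aa, Cd74, the invariant chain of class II molecules, rose from 53.8 ± 31.7 to 441 ± 99.9, H2-Eb1 from 105 ± 43.4 to 637 ± 124 and H2-Ab1 from 217 ± 86.9 to 1164 ± 221, with limma adjusted p between 9.46e-06 and 2.82e-05. These genes kept their direction and their call in every alternative setting. Among markers of immune cells, the T cell and intraepithelial lymphocyte list had a median of 0.96 (camera adjusted p = 0.000188; adjusted p = 0.378 with an estimated correlation). None of its 10 genes passed over all genes tested, and 6 were higher when adjusted over the list alone. Its largest changes on the log2 scale were those of Cd3e (9.66 ± 4.96 in WT and 21.1 ± 7.25 in null) and Cd7 (93.3 ± 30.6 and 192 ± 73.0). Of 5 B cell and plasma cell genes, Jchain, the joining chain of secreted antibodies, rose from 58.5 ± 43.1 to 294 ± 126 (limma adjusted p = 0.00331). The other 4 did not pass over all genes tested and 1 of them did when adjusted over the list alone. The list had a median of 0.77 (limma camera adjusted p = 0.113). None of the 3 measured macrophage genes passed, with a median of 0.11.

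Of the 11 measured genes of epithelial antimicrobial and inflammatory response, 4 rose, 1 fell and 6 did not pass; 5 rose and 2 fell when adjusted over the list alone. The list had a median log2 change of 1.03 (camera adjusted p = 0.00305; adjusted p = 0.378 with an estimated correlation). Reg3b rose by 2.77 on the log2 scale and Reg3g, a related antibacterial lectin, went from 1409 ± 545 to 8733 ± 4899. Duox2, an oxidase of the epithelial surface that produces hydrogen peroxide, rose from 5.07 ± 3.95 to 63.9 ± 18.2, and its maturation factor Duoxa2 from 34.6 ± 49.4 to 876 ± 490. The gene that fell was Reg3a, at 1383 ± 822 in WT and 462 ± 267 in null (chosen after its values were seen). Gpx2, a glutathione peroxidase of the gut epithelium, rose from 404 ± 260 to 3404 ± 548. The largest rise was that of Pla2g4c, a phospholipase A2, from 3.79 ± 1.004 to 1172 ± 1490 (log2 6.44, SE 0.96, limma adjusted p = 0.00101), and its null libraries ranged from 23.6 to 3542. The other genes among the 10 largest rises were Art2a-ps (log2 4.49), Gdpd3 (3.35), Sprr2a3 (3.25) and H2-DMb1 (3.06).

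**Figure D2:**
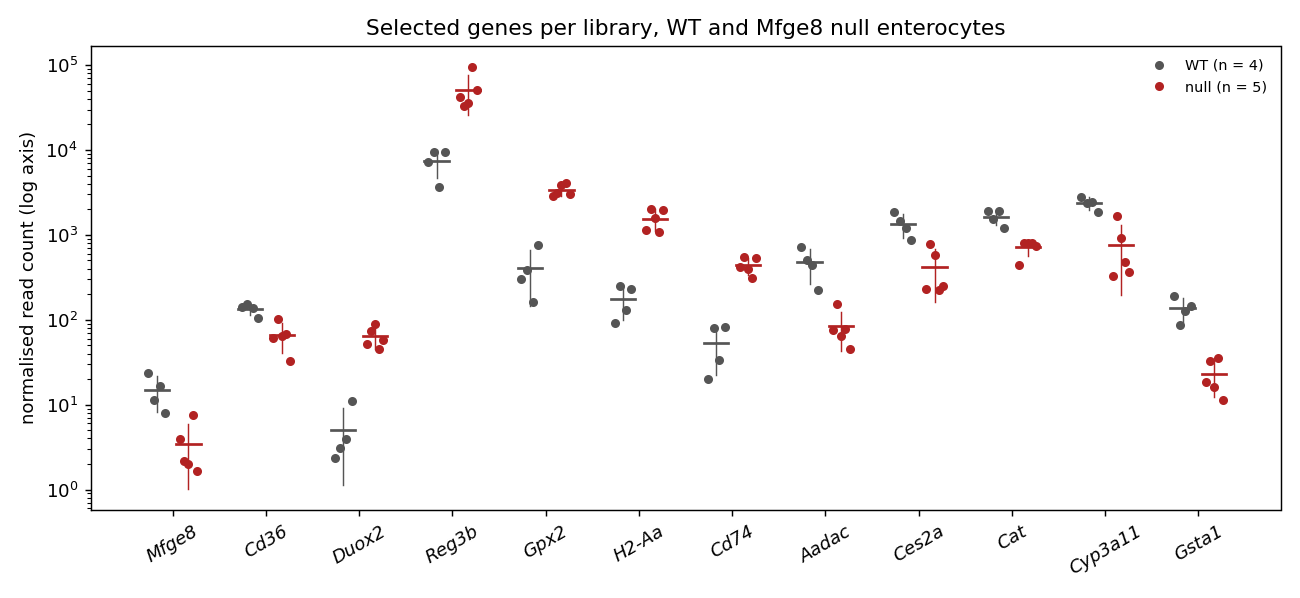
Normalised read counts (log axis) of 12 genes in each WT (grey, n = 4) and Mfge8 null (red, n = 5) enterocyte library; horizontal bars are means and vertical bars ± SD. Reg3b, Gpx2, Duox2, H2-Aa and Cd74 lie higher in all null libraries, and Mfge8, Cd36, Aadac, Ces2a, Cat, Cyp3a11 and Gsta1 lower.

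Of the 15 measured triglyceride lipases and carboxylesterases, 6 fell, 1 rose and 8 did not pass; 8 fell and 1 rose when adjusted over the list alone. The median log2 change was -0.65 (camera adjusted p = 3.37e-05; adjusted p = 0.338 with an estimated correlation). Besides Aadac, the carboxylesterases Ces1d (30.9 ± 13.9 to 3.21 ± 1.46), Ces1e (33.2 ± 18.1 to 6.16 ± 1.501) and Ces2a (1344 ± 414 to 417 ± 257) fell. The gene that rose was Pnliprp2, a lipase, from 13.2 ± 4.03 to 35.3 ± 8.45 (chosen after its values were seen). In peroxisomal and microsomal fatty acid oxidation 4 of 19 genes fell and none rose, with 6 lower when adjusted over the list alone and a median of -0.36 (camera adjusted p = 8.72e-05; adjusted p = 0.378 with an estimated correlation). Catalase (Cat) fell from 1642 ± 337 to 717 ± 155, and Acaa1b, Hsd17b4 and Phyh fell by 1.26, 0.88 and 0.64 on the log2 scale; these 3 calls held in 12, 11 and 8 of 21 alternative settings. In mitochondrial fatty acid oxidation 1 of 19 genes passed, 3 when adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.000303; adjusted p = 0.378 with an estimated correlation). That gene was Acaa2, the last thiolase of the pathway, which fell from 284 ± 109 to 79.0 ± 22.4. Among PPAR target genes 3 of 17 fell, 4 when adjusted over the list alone, with a median of -0.36 (camera adjusted p = 0.00305; adjusted p = 0.378 with an estimated correlation).

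Of the genes of fatty acid uptake and activation, Cd36 fell from 135 ± 20.2 to 65.8 ± 25.1 normalised reads in Mfge8 null enterocytes (limma adjusted p = 0.0234; exact permutation p = 0.0159). Acsl1, an acyl-CoA synthetase, fell from 102 ± 23.5 to 56.6 ± 14.4, and Slc27a4, a fatty acid transport protein, rose from 2331 ± 315 to 3566 ± 470. The call for Slc27a4 held in 4 of 21 alternative settings, that for Acsl1 in 11 and that for Cd36 in 15. The other 8 of the 11 genes did not pass. Adjusted over the list alone, 2 of all 11 rose and 3 fell, and the list had a median of 0.04, a mean of -0.08 and a camera adjusted p of 0.992. None of 16 genes of triglyceride synthesis and lipid droplets (median 0.16), 13 of chylomicron assembly (median 0.01, mean and test negative) and 9 of sterol absorption (median 0.22) passed over all genes tested. Of 25 genes of cholesterol biosynthesis, Sqle rose from 42.3 ± 15.8 to 93.6 ± 20.8 (list median 0.22, limma camera adjusted p = 0.0961). Of 11 genes of fatty acid synthesis, Elovl1 rose from 174 ± 16.0 to 312 ± 64.1 (list median -0.05, mean 0.14 and test positive).

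In xenobiotic metabolism 5 of 16 genes fell, with 6 lower and 1 higher when adjusted over the list alone and a median of -0.79 (camera adjusted p = 0.000111; adjusted p = 0.378 with an estimated correlation). Cyp3a11, a cytochrome P450 of drug metabolism, fell from 2372 ± 401 to 751 ± 558, Cyp2j6 from 1295 ± 465 to 538 ± 122 and Cyp3a25 from 1043 ± 196 to 455 ± 245. In glutathione and oxidative stress defence 5 of 17 genes fell and 2 rose, with 8 lower and 2 higher when adjusted over the list alone and a median of -0.27 (camera adjusted p = 0.00620; adjusted p = 0.378 with an estimated correlation). The glutathione transferases Gsta1 (137 ± 42.9 to 22.9 ± 10.6), Gsta4 (118 ± 35.0 to 23.5 ± 5.81) and Gstm1 (209 ± 19.3 to 79.5 ± 41.5) fell. By the rule for named genes, the largest falls were those of the tripartite motif genes Trim12a and Trim34a. Trim12a went from 75.4 ± 6.37 to 0.392 ± 0.876 (log2 -5.94, SE 0.42, limma adjusted p = 7.64e-07) and Trim34a from 21.4 ± 3.06 to 0.214 ± 0.479. They were followed by Akr1c14 (log2 -3.68), Trim30d (-3.21), Ces1d (-2.92), Lect2 (-2.86), Ccl24 (-2.83), Gsta1 (-2.60), Akr1c19 (-2.59) and Aadac (-2.49). Near-identical copies of the Trim, Akr1c, Ces, Gsta, H2 and Sprr2 families can share reads, so the values of single members are uncertain.

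In unfolded protein and integrated stress response 1 of 15 genes, the chaperone Hsp90b1, rose (735 ± 62.9 to 1084 ± 87.7), with 4 when adjusted over the list alone and a median of 0.33 (camera adjusted p = 0.00148; adjusted p = 0.338 with an estimated correlation). The call for Hsp90b1 held in 11 of 21 alternative settings and that for Dpp4 in 8. In peptide and amino acid absorption 1 of 15, the peptidase Dpp4, rose (1724 ± 412 to 2814 ± 532), with 3 when adjusted over the list alone and a median of 0.42 (camera adjusted p = 0.00148; adjusted p = 0.378 with an estimated correlation). No gene of 17 of cell proliferation passed either adjustment, with a median of 0.54 (camera adjusted p = 0.00148; adjusted p = 0.378 with an estimated correlation). Of 13 enteroendocrine genes Reg4 fell (1677 ± 279 to 790 ± 206), with 2 lower when adjusted over the list alone and a median of -0.53 (camera adjusted p = 0.00148; adjusted p = 0.378 with an estimated correlation). Of 20 interferon response genes Usp18 (20.6 ± 1.14 to 43.9 ± 6.24) and Zbp1 (20.3 ± 7.10 to 52.9 ± 14.1) rose, with 3 when adjusted over the list alone and a median of 0.22 (camera adjusted p = 0.0391; adjusted p = 0.602 with an estimated correlation). The interferon call was lost in 13 alternative settings.

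Of 5 ileal genes Slc51b, a bile acid exporter subunit, rose (263 ± 10.01 to 466 ± 83.0), with 2 when adjusted over the list alone and a median of 0.58 (camera adjusted p = 0.0105; adjusted p = 0.378 with an estimated correlation). Of 6 proximal genes the transcription factor Onecut2 fell (153 ± 23.9 to 72.9 ± 43.3), with 3 lower when adjusted over the list alone and a median of -0.66 (camera adjusted p = 0.0174; adjusted p = 0.378 with an estimated correlation). The call for Onecut2 held in 11 of 21 alternative settings. Fabp6, the ileal bile acid-binding protein, ranged from 43.3 to 8959 over WT libraries and from 34.3 to 6807 over null libraries, and its change did not pass (log2 0.57, SE 1.34, limma adjusted p = 0.890), with arithmetic means of 2454 and 2150. A regional score, the mean of proximal markers minus that of ileal markers, ranged from -1.04 to 1.07 in WT and from -2.17 to 0.765 in null libraries. The genotypes overlapped, with null 4 at 0.765, but the lowest scores were those of null 3 (-1.75) and null 5 (-2.17). Region was therefore not balanced between the genotypes. With a regional score of these markers as a covariate, an alternative chosen after seeing the data, 189 genes and 13 lists passed.

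In total 16 of 36 lists passed by camera with a preset correlation of 0.01, 8 higher and 8 lower. With an estimated correlation camera called 0 lists, and 3 had an unadjusted p under 0.05. The alternative fry, which tests whether the genes of a list move on balance in 1 direction, called 4. These were MHC class II (fry adjusted p = 0.00102), triglyceride lipases and carboxylesterases (0.0188), unfolded protein and integrated stress response (0.0188) and glutathione and oxidative stress defence (0.0469). Lists that did not pass by camera, with their medians, were bile acid handling (0.58; Slc51b rose), tuft cells (0.47), immediate early and heat shock genes (0.24), intestinal stem cells (0.19), MFGE8 receptors and related integrin pathway genes (0.09), insulin and mTOR signalling (0.04) and oxidative phosphorylation (0.02; Ndufa4 fell by 0.61, a call that held in 10 of 21 alternative settings). The medians were -0.38 for carbohydrate digestion (Fbp1 fell by 1.54), -0.17 for circadian clock, -0.04 for ribosomal proteins, -0.01 for goblet cells, where camera and fry differed in sign, and -0.00011 for Paneth cells, whose mean was 0.12 and test positive. Too few genes were measured to test mast cells (1), smooth muscle (1), endothelium (2), enteric neurons and glia (1), adipocytes (1), exocrine pancreas (1), erythroid cells (1) and fibroblasts (0), and no measured gene of these lists passed over all genes tested.

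**Figure D3:**
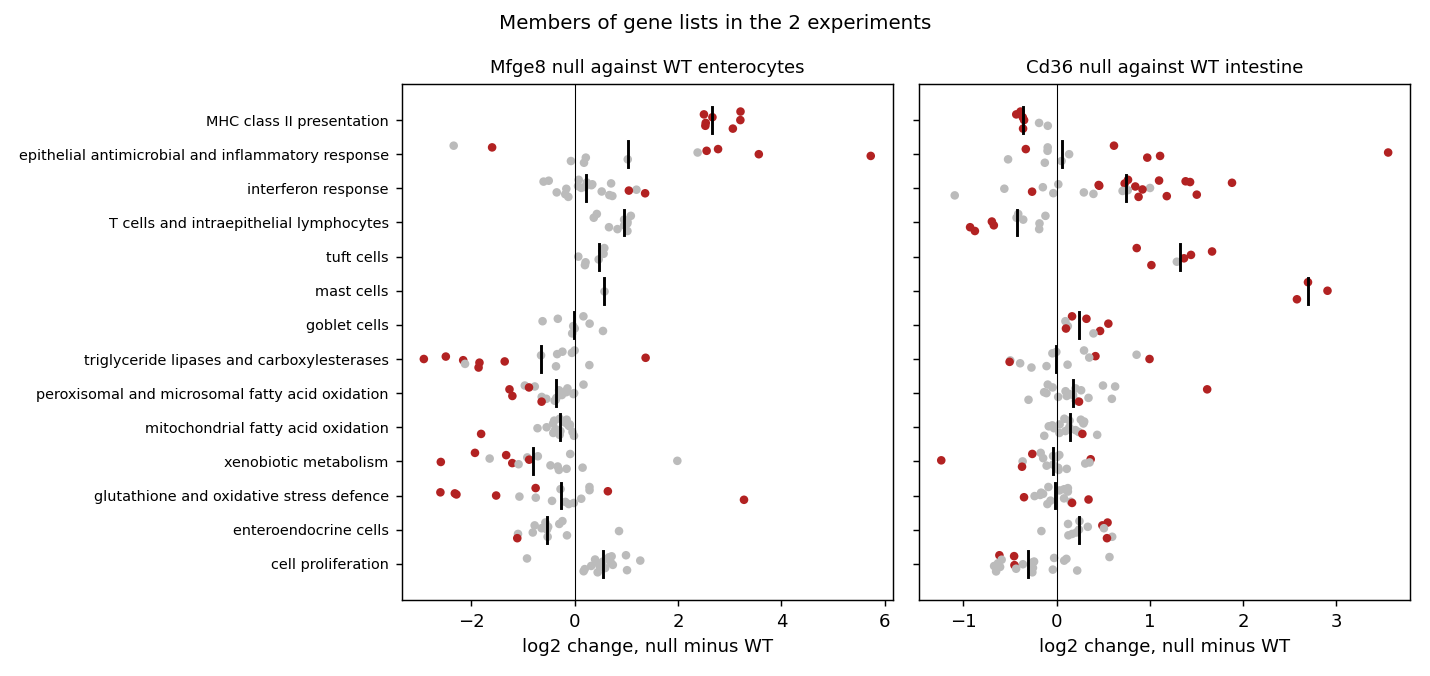
Log2 change (null minus WT) of each measured member of 14 gene lists in both experiments; red points passed the limma threshold over all genes tested, grey points did not, black bars are list medians, and the horizontal scales of the panels differ. MHC class II genes have a median of 2.67 in Mfge8 null enterocytes and -0.36 in Cd36 null intestine.

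Genes that changed were more frequent near the disrupted Mfge8 locus. Within 10 Mb of Mfge8, 7 of 50 tested genes (14%) passed, against 294 of 9360 (3.14%) elsewhere, an odds ratio of 5.02 with a 95% interval of 1.89 to 11.4 (Fisher's exact p = 0.000980). Hddc3, which starts at position 80343075, rose from 2.25 ± 0.658 to 19.2 ± 6.17 normalised reads in Mfge8 null enterocytes. Ngrn rose from 118 ± 14.6 to 213 ± 13.6 and Homer2 fell from 291 ± 23.9 to 103 ± 13.6 (these 3 genes were chosen after their values were seen). Hddc3, Ngrn and Eftud1, also within 10 Mb, were higher in Cd36 null intestine too, by log2 changes of 3.93, 0.54 and 0.395. The targeted gene there lies on chromosome 5, so these rises were not particular to the Mfge8 null line. Homer2 did not pass in both experiments.

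The intestine comparison addressed which genes differ when Cd36 is absent. Cd36 (chromosome 5, 17781690 to 17888959, mm10) was at 114 normalised reads (range over libraries 111 to 116) in WT intestine and 12.6 (6.48 to 16.0) in null intestine, 11.1% of WT. The exact permutation test over libraries gave p = 0.0286, the smallest value that the 35 splits can give. Because the libraries of each genotype agreed at about sampling noise, this and every other p in this comparison measures the spread between these libraries, and not a known spread between mice. The difference between genotypes has no replicate check. Mfge8 was at 11.96 and 14.2 normalised reads in WT and null intestine.

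In the Cd36 null preparation 13 of 24 interferon response genes, 5 of 6 tuft cell genes and 3 of 3 mast cell genes were higher than in the WT preparation, and 4 of 10 lymphocyte genes and 5 of 7 MHC class II genes were lower. With an estimated correlation the adjusted p was 0.0201 for the interferon and tuft cell lists, 0.0532 for mast cells, 0.0602 for MHC class II and 0.138 for lymphocytes. The correlation was estimated between libraries that agreed at about sampling noise, so it leaves out correlation between mice. By limma 699 of 9314 genes differed beyond the spread between libraries, 392 higher and 307 lower in the null preparation, and 164 differed by more than 1 on the log2 scale. With the reads summed per genotype and the spread of the Mfge8 experiment assumed, an alternative chosen after seeing the data, 28 genes passed. That spread was 1 value for all genes, a biological coefficient of variation of 22.5%. It does not cover genes that vary more between libraries, as Fabp6 did among enterocyte libraries. The ranks that follow are among genes that the rule for named genes admits, with a higher group mean of at least 20 and without Cd36 itself. The largest rises were those of Fn1, which encodes fibronectin (1.01 to 28.6 normalised reads, null libraries 22.2 to 38.0), Hddc3 (2.29 to 48.8), Retnlb, a goblet cell protein (3.71 to 32.9), and H2-Bl (5.35 to 68.9). They were followed by Mcpt2 (9.41 to 77.1), Mcpt1 (24.2 to 153), Gdpd3 (6.86 to 49.995), Mptx1 (17.4 to 80.4), Nrgn (9.81 to 40.6) and Ifit1bl1 (134 to 495). The largest falls among the admitted genes were those of Fam132a (75.9 to 17.1), Nlrp9b (51.9 to 12.5) and Fabp6 (278 to 69.2, null libraries 62.9 to 77.7). Il7r (26.1 to 7.06) and Plb1, a phospholipase (150 to 47.8), came next. Ern2, Smim6, Rora, Ubd and Nlrc4 were lower by log2 changes of -1.62, -1.62, -1.62, -1.58 and -1.53. Trim34a, Trim12a and Rps15a, with group means below 20, fell further (log2 -4.07, -4.03 and -2.64).

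Of 24 interferon response genes 13 were higher and 1 lower in the Cd36 null preparation (17 and 3 when adjusted over the list alone). Their median log2 difference was 0.75, at percentile 100 among 10000 random lists of matched expression. Extreme percentiles were common in this comparison. An upper tail that would hold 0.875 lists by chance held 14 of 35, and the equal lower tail held 8. Random lists do not carry the correlation between genes of a list, so a percentile near either end does not show a rare event. Ifit1 was at 158 in WT and 338 in null (330.3 to 353), Xaf1 at 25.4 and 73.6, and Rtp4 at 70.8 and 131. Of 6 tuft cell genes 5 were higher (6 when adjusted over the list alone), with a median of 1.33 at percentile 100. Among them Alox5ap, a protein of leukotriene synthesis, was at 31.7 and 83.2 (80.5 to 87.0), Avil at 14.8 and 41.1 and Dclk1 at 40.8 and 74.8. All 3 measured mast cell genes were higher, Mcpt1, Mcpt2 and Cpa3 (0.776 and 8.79), with a median of 2.69 at percentile 99.99 and a camera adjusted p = 0.0532 with an estimated correlation. Of 8 goblet cell genes 5 were higher (6 over the list alone), with a median of 0.24 at percentile 99.91 (adjusted p = 0.0614 with an estimated correlation). Clca1 was at 1237 and 1816 and Tff3 at 702 and 876.

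The T cell and intraepithelial lymphocyte list had 4 of 10 genes lower in the Cd36 null preparation (6 when adjusted over the list alone), with a median of -0.42 at percentile 0 (adjusted p = 0.138 with an estimated correlation). Ccl5, a chemokine of lymphocytes, was at 337 and 182 normalised reads in WT and null, Gzmb at 149 and 92.9 and Itgae at 49.2 and 25.7. Of 7 MHC class II genes 5 were lower by either adjustment, with a median of -0.36 at percentile 0 (adjusted p = 0.0602 with an estimated correlation). H2-Ab1 was at 1360 and 1007 and H2-Aa at 1198 and 915. Of 20 proliferation genes 3 were lower by either adjustment (median -0.31, percentile 0.08, camera adjusted p = 0.0713 with an estimated correlation). Among them were Mki67 (93.1 and 59.8) and Top2a (164 and 119). Of 9 Paneth cell genes 1 was higher and 4 lower (1 and 5 over the list alone), with Ang4 at 116 and 165 and Defa21 at 106 and 67.3. The Paneth cell list had a median of -0.31 at percentile 0 (camera adjusted p = 0.137 with an estimated correlation). Of 6 ileal genes Fgf15 was higher (7.84 and 24.8) and 2 were lower, Fabp6 among them (median -0.23, percentile 0.65).

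Lists of lipid and sugar handling had medians from -0.09 (sterol absorption) to 0.18 (peroxisomal and microsomal fatty acid oxidation) between the Cd36 preparations, while single genes differed more. Of 11 genes of fatty acid uptake and activation 4 were higher and 2 lower (4 and 3 over the list alone; median 0.15, percentile 97.87), with Fabp1 at 3367 in WT and 4011 in null and Fabp2 at 9324 and 7764. Of 13 chylomicron genes Apoa1 (6524 and 8012) and Apoa4 (2014 and 2506) were higher (median 0.08, percentile 81.66; 5 higher and 1 lower over the list alone). Of 13 genes of carbohydrate digestion 6 were higher (8 over the list alone), with Pck1, an enzyme of gluconeogenesis, at 272 and 458. The carbohydrate list had a median of 0.16 at percentile 99.44 (camera adjusted p = 0.110 with an estimated correlation). Dgat2, of triglyceride synthesis, was at 104 and 162, and Me1, of fatty acid synthesis, at 14.3 and 48.9. Lpin1 was at 15.5 and 28.9, the lipase Pnliprp2 at 47.3 and 94.8 and Acaa1b at 2.74 and 8.60. The medians of the lists of triglyceride and fatty acid synthesis were 0.02 (percentile 51.98) and 0.09 (percentile 89), each with 2 genes higher.

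By camera with the preset correlation 15 of 35 lists differed between the preparations, 11 higher and 4 lower. With an estimated correlation the interferon and tuft cell lists remained (camera adjusted p = 0.0201 for both), and the other 13 had adjusted p of 0.0532 to 0.294. The estimates for these 2 lists were -0.0212 (interferon) and 0.0019 (tuft cells), against 0.339 and 0.205 in the Mfge8 experiment. They came from libraries that agreed at about sampling noise, so correlation between mice could not enter this check. Of the lists above, ileal genes and chylomicron assembly (camera adjusted p = 0.128 for both) and fatty acid uptake (0.198) were not called. Neither were triglyceride synthesis (0.2003) and fatty acid synthesis (0.225). The called lists not described above were enteroendocrine cells (3 of 13 higher, median 0.24), immediate early and heat shock genes (4 of 18 higher and 1 lower, 0.22) and mitochondrial fatty acid oxidation (1 of 19 higher, 0.14). Cholesterol biosynthesis (0 of 23, 0.14), PPAR target genes (3 of 14 higher, 0.14) and oxidative phosphorylation (5 of 42 higher, 0.09) were called too. Lists not called by camera included peroxisomal and microsomal fatty acid oxidation (median 0.18), circadian clock (0.14), proximal genes (0.09), MFGE8 receptors (0.07), antimicrobial and inflammatory response (0.05, with Duox2 at 57.0 and 124 and Reg3b at 7943 and 6314) and triglyceride lipases (-0.0037, mean 0.09 and test positive). Their medians were -0.02 for glutathione and oxidative stress defence, where the test was positive, -0.03 for insulin and mTOR signalling, where mean and fry were positive, -0.04 for xenobiotic metabolism, -0.05 for peptide absorption and -0.07 for ribosomal proteins. The remaining ones were sterol absorption (-0.09), unfolded protein response (-0.11), bile acid handling (-0.16) and intestinal stem cells (-0.33, Sox9 higher). Of markers too few to test, Dcn of fibroblasts was at 19.9 and 8.43, Mylk of smooth muscle at 636 and 706 and Clps of exocrine pancreas at 76.1 and 113. Lyve1 of endothelium, Aqp7 of adipocytes and Itgax of myeloid cells did not pass, and no B cell, neuronal or erythroid marker list had 3 measured genes. Near Cd36, 4 of 43 genes within 10 Mb differed, against 692 of 9251 elsewhere (odds ratio 1.27, 95% interval 0.328 to 3.53, Fisher's exact p = 0.561).

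Of the 75 genes that passed in both experiments, 14 lay on chromosome 7, 13 of them with the same direction, and 61 elsewhere, 30 of them with the same direction. On chromosome 7, Trim34a, Trim12a and Trim30d were lower, and Gdpd3, Hddc3, Pla2g4c and Fut2 higher, in both null lines. Trim12a and Trim34a had 0 reads in all 3 Cd36 null libraries, against 15.9 and 16.2 normalised reads in WT, at least 16.5-fold and 16.8-fold lower with a floor of 3 reads over the group. Rps15a was lower in both, by log2 changes of -1.52 in Mfge8 null and -2.64 in Cd36 null. Gsdmc2, a gasdermin on chromosome 15, was higher in both (2.89 and 1.59). Ubd was higher in Mfge8 null enterocytes (2.60) and lower in the Cd36 null preparation (-1.58). Of 8560 genes tested in both, 75 passed in both, 33 higher in both (6.05 expected from independent lists, Fisher's exact p = 4.40e-16), 10 lower in both (4.71 expected, p = 0.0275) and 32 in opposite directions. Without chromosome 7, an alternative chosen after seeing the data, 26 genes were higher in both (Fisher's exact p = 2.98e-12) and 4 lower. No expected number was computed for the 32 genes in opposite directions. Off chromosome 7 the directions agreed for 30 of 61 genes, so these p-values alone do not show a shared response. Without Mfge8 WT 1 the genes that passed in the same direction were 28 in place of 43. The experiments share no library. Across genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.041 and a Spearman correlation of 0.006. Exchanging libraries between groups gave Pearson values of -0.120 to 0.1696, with 41 of 100 draws as large.

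The change differed between the experiments for 235 of 8560 genes by limma, 125 more positive and 110 more negative in the Mfge8 experiment. The largest positive differences were those of Duoxa2 (log2 4.76, SE 1.01, limma adjusted p = 0.00887), Pla2g4c (4.595), Ubd (4.18), H2-Aa (3.60, SE 0.35, adjusted p = 3.63e-06) and Cd74 (3.56). The largest negative ones were those of Akr1c14 (-4.26, SE 0.77, limma adjusted p = 0.00294), H2-Bl (-3.44), Ccl24 (-3.44), Acaa1b (-2.87) and Aadac (-2.84). This fit pooled the spread between enterocyte libraries with the spread of the intestine libraries, and sample type and targeted gene differed together. Xist reads were found in every intestine library and in no enterocyte library, so the sexes of the mice differed with them. The count ranged from 146 without Cd36 null 1 or null 2 and 152 without Cd36 null 3 to 377 without Mfge8 null 2 and 378 without Mfge8 WT 4.

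**Figure D4:**
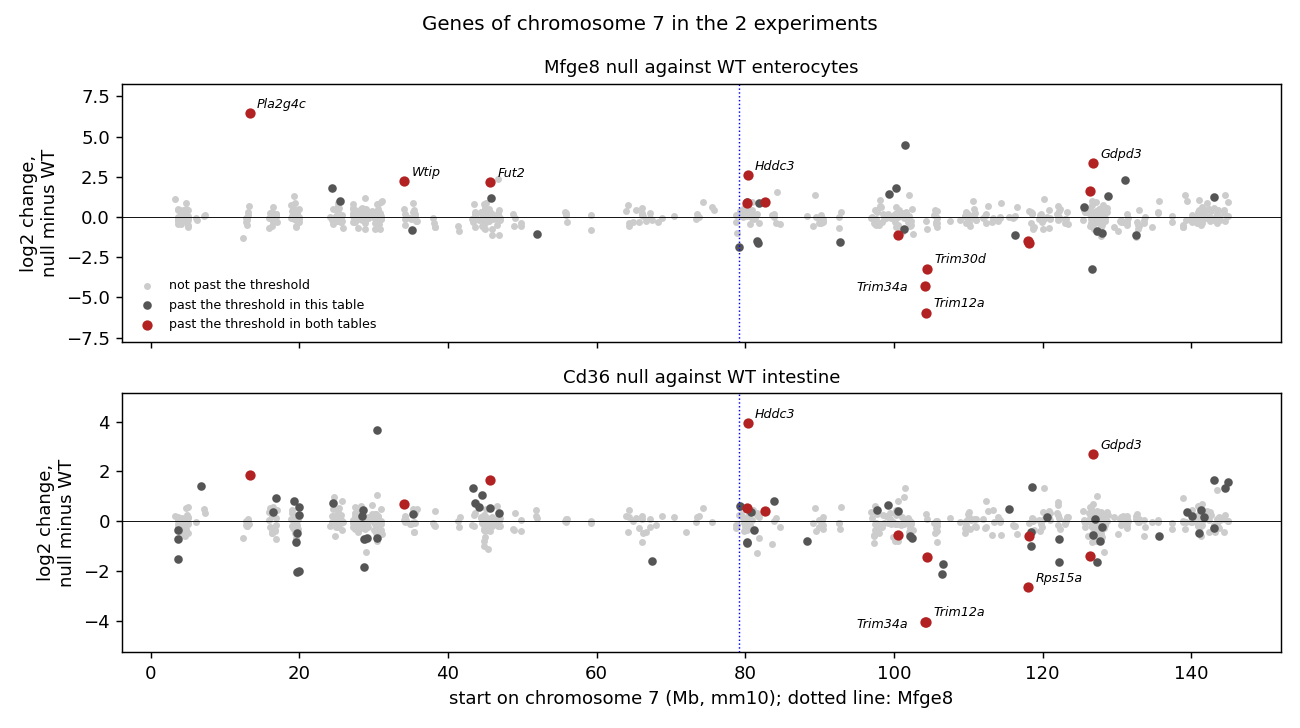
Log2 change (null minus WT) of genes along chromosome 7 (start in Mb, mm10) in both experiments; red points passed the limma threshold in both tables, dark points only in the table shown, grey points did not pass in that table, and the dotted line marks Mfge8. Trim12a and Trim34a lie lowest in both panels, at -5.94 and -4.27 in Mfge8 null enterocytes.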

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

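The tests of both sexes, chromosome 7, and MHC class II genes below were chosen only after the result was seen; the thinning test and the counts over other splits of the libraries were fixed first.

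Of 108 groups of library values checked in the Mfge8 experiment, 7 held a library far from the others, where chance gives 5.4; the Cd36 experiment was not checked because it counted as 1 sample per genotype. WT 3 had 2459812 reads, against 1618369 to 1756643 in the other WT libraries. Trim12a was at 1.96 in null 1 and 0 in the other null libraries, and Trim34a at 1.07 in null 4 and 0 in the others. Akr1c14 was at 8.99 in null 3, against 0 to 2.46. Acaa2 was at 447 in WT 1, against 225 to 236. Cat was lowest in null 1 at 446, against 732 to 808, and Fbp1 lowest in null 3 at 9.99, against 17.2 to 19.6.

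Other splits of the same libraries into groups of the same sizes show how far chance reaches. For genes changed in Mfge8 null enterocytes, 1 of 100 splits, the real one, gave as many as 303, and the highest other gave 183. This argues against chance between these libraries, but the labels do not say that they came from separate mice. For gene lists in that comparison 16 of 100 splits gave 16 or more, with a highest other of 21 and a median of 7 over the other splits, so chance cannot be excluded for the number of lists. In the Cd36 experiment 1 of 35 splits, the real one, gave 699 genes (highest other 130). This argues against chance between these libraries but not between mice. For lists 1 of 35 splits gave 15, with a highest other of 14 and a median of 0 over the other splits. The margin for lists was thus small, and a first rank among 35 splits is the lowest share that this check can give. For genes whose change differed between the experiments 1 of 100 splits gave 235 (highest other 14). The Cd36 libraries entered as technical samples here too, so this rank cannot decide about chance between mice.

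Libraries of 1 genotype in the Cd36 experiment agreed at about sampling noise. Shallow depth is argued against: thinned to 865512 reads, the enterocyte libraries still had a lowest chi-square per degree of freedom of 4.16 within a genotype. A candidate explanation is 1 pool of RNA per genotype from mice of both sexes, since 7 of 7 libraries held Xist and Y-linked genes, against 0 of 9 in the Mfge8 experiment; Xist was lower in the null libraries (log2 -0.47). Genotype and any other difference between the 2 preparations remain open.

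Of 14 genes on chromosome 7 that passed in both experiments 13 changed in the same direction, against 30 of 61 elsewhere (Fisher's exact p = 0.00262), and the Pearson correlation across its genes was 0.421, where the highest of the other chromosomes was 0.116 (Spearman 0.0981 on chromosome 7 and 0.0872 on chromosome 10). The chromosome was picked because its genes changed alike and neighbouring genes are not independent, so both values restate the pattern; DNA of another mouse strain in both null lines and a response that does not depend on position cannot be told apart by them. The shared genes lie from Pla2g4c at 13311507 to Gdpd3 at 126766414. RNA of Mfge8 null mice in the Cd36 null preparation is argued against, because the log2 change of Mfge8 there was 0.252. No genotype calls were analysed here, and shared reads among Trim copies stay open.

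MHC class II genes were higher in Mfge8 null enterocytes. For macrophages, the summed rises of the 9 myeloid genes were 3.03% of the rise of Cd74 and 11.2% with 2 standard errors added. This argues against macrophages as the whole source only if such cells hold these genes at levels comparable to Cd74, which was not measured here. B cells or plasma cells cannot be told apart from a rise in enterocytes, because 8 of their genes summed to 66.6%, nearly all from Jchain (60.7%), and the rise of Cd79b was 0.373% of that of Cd74; dendritic cells were not tested. A more distal origin of the null libraries as the whole cause is argued against: with a regional score as covariate the median log2 change was 2.59, against 2.67 without, and 7 of 7 genes passed. Genotype, and housing or microbial exposure that may differ between the lines, stay open and untested.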

How the results depend on the processing

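The tests with a regional covariate, with summed reads, without chromosome 7 and with 2 libraries left out of the count test were chosen only after the result was seen. No named gene changed direction in any setting run. Genes changed in Mfge8 null enterocytes were 303 as reported, 147 with no trend, 189 with the regional covariate, and 140 to 388 without 1 library; other settings gave 229 to 430. Called lists there were 16, 0 with an estimated correlation and 4 by fry. Genes in the Cd36 comparison were 699, 229 with no trend, 318 with DESeq2, and 28 with reads summed per genotype and the Mfge8 spread assumed; called lists were 15, 2 with an estimated correlation and 24 by fry. The log2 change of Cd36 without 1 library was -3.38 to -2.79, with exact permutation p of 0.0667 to 0.1, because fewer splits cannot give a p under 0.05. Genes passing in both experiments in 1 direction were 43, 28 to 43 without 1 library (28 without Mfge8 WT 1), 30 without chromosome 7 and 183 at unadjusted p. The correlation of fold changes was 0.041 and -0.030 without chromosome 7. Genes differing between experiments were 235, and 146 to 378 without 1 library. The locus results kept their side of the threshold in every setting run. Of 53 named genes of the Mfge8 comparison, 35 kept their call with no trend and 41 with the covariate; of 107 in the Cd36 comparison, 48 kept it with no trend and 14 with summed reads. Except where stated, the cause was not tested. With the replicate block, counts were 229 and 643 genes, 16 and 13 lists, and 156 genes differing between experiments; same-numbered libraries correlated at -0.12 to 0.21 (Mfge8) and -0.015 to 0.0033 (Cd36), and 1 of 4 and 0 of 4 WT libraries matched their own number best, so numbers were not taken as pairs. Depth limits low genes: Mfge8 had 2 to 21 reads per enterocyte library.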

Other observations

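The genes below were chosen only after their values were seen, and the tests are the limma calls of the main comparisons.

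Gsdmc2, Gsdmc3 and Gsdmc4, pore-forming gasdermins on chromosome 15, were the 3 Gsdmc genes that passed the expression filter in both experiments, and each passed the limma threshold in both. In Mfge8 null enterocytes Gsdmc2 rose from 11.5 ± 6.28 to 94.0 ± 51.2, Gsdmc3 from 4.83 ± 2.87 to 31.3 ± 19.6 and Gsdmc4 from 43.0 ± 30.5 to 199 ± 97.4 normalised reads (SD, n = 4 WT and 5 null libraries). In the Cd36 null preparation Gsdmc2 was at 63.1 against 21.6 in WT, Gsdmc3 at 41.6 against 15.2 and Gsdmc4 at 408 against 166. These genes are near-identical copies, so reads can be shared among them. Tnfrsf21, a death receptor, also rose in Mfge8 null enterocytes, from 28.5 ± 8.04 to 78.0 ± 32.9, and was at 89.4 against 30.2 in the Cd36 preparations.

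Car4, a membrane carbonic anhydrase, rose from 47.8 ± 26.5 to 312 ± 105 in Mfge8 null enterocytes, and Oxct1, an enzyme of ketone body use, from 145 ± 16.4 to 491 ± 140.4. In the Cd36 preparations Car4 was at 515 in WT and 653 in null, and Oxct1 at 559 and 740.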
